A study of Homo sapiens with 4 samples.

How the data were processed

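RNA from 4 samples of macrophages derived from THP-1, a human monocytic leukaemia line, was measured on human oligonucleotide arrays, 1 array per sample with a single dye (Cy5). Per the labels' protocols, THP-1 cells were turned into macrophages with the phorbol ester PMA (100 ng/ml for 24 h), total RNA was taken up in Trizol and amplified, and the amplified RNA was labelled through amino allyl coupling. Samples were grouped by the labels: 2 samples of macrophages alone (control 1 and control 2), 1 co-cultured for 48 h with HepG2 cells and 1 co-cultured for 48 h with MHCC-97H cells. The treatment label of the controls reads untreated, while the protocol text calls the comparison group macrophages, so both controls were taken as PMA-treated THP-1 cells kept without cancer cells. No label says whether the 2 controls came from separate cultures or were handled on separate days, so p-values measure only the spread between these samples, which can be technical.

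The deposited raw values are whole-number intensities, and they include negative numbers, so background had been subtracted before deposit. The authors' normalized intensity equals the raw intensity times 1 constant per array: 0.8487 for control 1, 1.0075 for control 2, 1.1034 for MHCC-97H and 1.0837 for HepG2. The deposited value table of the series holds the same normalized values within 5.0e-07. Each probe also has a detection p-value per array, per the file headers, and a flag score from the authors, which took only 2 values and was not used because its meaning is not stated. The authors' comparison columns hold a log2 ratio and a p-value for 2 array pairs, HepG2 co-culture with control 1 and MHCC-97H co-culture with control 2. Among all probes, 2149 for HepG2 and 456 for MHCC-97H had a log2 ratio of at least 1 in size and a p-value under 0.05. The authors called 2153 and 466 probes, and whether these are the same probes was not checked. The deposited log2 ratios stop at 6.64, a 100.0-fold change, which 12 probes reach in the HepG2 pair. The scanner, its software and the error model behind these p-values are not given in the sources used here. A further sheet that repeats part of the normalized values was not used here.

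From the normalized intensities, values under 100 were set to 100 and the log2 was taken. Of the probes, 25766 carried 1 gene symbol, 1130 several and 1368 none, and probes with several or none were not named or tested. Symbols were updated through the Entrez gene identifiers with a RefSeq gene table (GRCh38.p14), which changed 1691 symbols and left 84 probes under the file's symbol. No coordinates are given, because the sources used here name no genome build for the probes. A gene was tested if its probe had a detection p-value under 0.01 on at least 1 array, and the brightest probe stood for the gene, which left 11010 genes. Second probes were compared only for the genes that separated the array pairs.

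Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. The joint comparison set both co-cultures against both controls, with 2 residual degrees of freedom. The comparisons of single lines came from a fit with 3 groups and 1 residual degree of freedom, so the lone sample of each line is assumed to vary like the controls. Fold counts within array pairs took genes at least 2-fold apart and have no test. The 26 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. With an estimated correlation, camera tests on the residual degrees of freedom of the fit, only 2 or 1 here. Hardly any list could pass there, so a call lost in that setting says little about the list. Each list's median was also set against 10000 random lists of the same size matched on mean level. Random lists hold genes drawn independently, while members of a list can move together. Between the 2 controls, 9 of the 26 lists lay above the random range and 8 below it. Lying outside that range therefore does not by itself mark a co-culture or a line. Lists, tests and the naming rule were fixed before the data were examined, while the floor of 100, the detection threshold and the counts over all 4 differences were chosen after seeing the data. The naming rule was S100A9 and S100A8 always, then the 10 highest and 10 lowest changes past the threshold that were at least 2-fold in both pairs. Where fewer passed, places were filled by genes at least 2-fold apart in all 4 differences between a co-culture and a control, ranked by the smallest. For each line the fill took genes at least 2-fold from both controls, and between the lines the 5 largest differences each way. Up to 4 members with the largest absolute change were named per list. A gene detected on only 1 array of a group, with the other group detected, is given as a log2 difference without a fold. A gene detected on no array of a group has only a bound there, so its fold is written as at least N-fold: the bright group's mean over, per array, the higher of the gene's own signal and the lowest detected signal.

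On simulated data for the joint comparison, with 200 of 11010 genes changed, limma recovered 0 of 50 genes changed by 1 on the log2 scale, 26 of 50 at 2, 47 of 50 at 4 and 48 of 50 at 6, with 2 false calls. For a lone sample against 2 controls it recovered 0 of 50 at 4 and 33 of 50 at 6, with 3 false calls. Each gene's spread was drawn independently of its change. In the data S100A8, with a joint change of 5.26, differed by 3.32 between the controls. The simulated recovery therefore need not hold for these arrays. In a simulated list test the shifted list was called and 0 of 25 others were. Genes were simulated as independent there, so it does not measure false calls among correlated genes.

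The pairs of the authors' comparison sheets were checked as a block. Across genes, the deviations of the HepG2 co-culture and control 1 from their group means correlated at r = 0.377, and genes are not independent replicates. Only these sheets, and no label, pair the arrays. Alternatives covered quantile normalization and median centring of the raw intensities, normexp correction (offset 50), the deposited value table, other detection filters and floors, the mean over a gene's probes, trended and robust variance priors, the pair as a block, crossed pairs, other fold thresholds and leaving out each sample. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.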

Results

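Gene expression was measured in macrophages derived from the monocytic leukaemia line THP-1, either kept alone (2 samples, control 1 and control 2) or grown for 48 h in the lower chamber of a transwell under cancer cells. The upper chamber held HepG2, a hepatoblastoma-derived liver cancer line, in 1 culture and MHCC-97H, a hepatocellular carcinoma line selected for metastasis, in the other. A porous membrane kept the cell layers apart, so the arrays were meant to read macrophage RNA only. Control 1 had 14064 detected probes (49.8%), control 2 had 12634 (44.7%), the MHCC-97H array 12551 (44.4%) and the HepG2 array 12925 (45.7%). The number of arrays limits the precision of every value, since each co-culture stands on a single sample. Levels are given as log2 of the authors' normalized intensity, and changes as the log2 difference ± its standard error in limma.

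The series title names S100A9, and the joint comparison asked how macrophages under either cancer line differed from macrophages alone. S100A8 and S100A9, the 2 subunits of the secreted alarmin calprotectin, were higher in both co-cultures than in both controls. S100A9 stood at 16.15 under HepG2 and 16.07 under MHCC-97H, against 9.74 in control 1 and 12.53 in control 2, a difference of 4.97 ± 0.91 (31.3-fold; n = 2 against 2). The normalized intensities of S100A8 were 63434 and 60816 against 512 and 5124, a difference of 5.26 ± 1.07. S100A8 was not detected in control 1, so this difference has no exact fold. S100A12, the third calgranulin, was not detected in either control and was at least 4.46-fold higher in the co-cultures. None of these passed the adjusted threshold (limma, adjusted p = 0.384 for S100A8 and for S100A9, 0.201 for S100A12).

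Several other genes stood far above both controls on both co-culture arrays. SLC16A9, a member of the monocarboxylate transporter family, had the widest margin, at 13.55 under MHCC-97H and 12.88 under HepG2 against 7.56 and 8.41 (at least 12.6-fold, difference 5.23 ± 0.40). The fructose transporter gene SLC2A5 was at least 11.2-fold higher and ACKR3, an atypical receptor for the chemokine CXCL12, at least 4.75-fold. PTGES, which encodes a prostaglandin E synthase, was higher by 4.13 ± 0.62 (5.05 against control 1 alone, 3.21 against control 2 alone) and the Src-like adaptor gene SLA by 4.12 ± 0.45 (4.74 and 3.50). TMEM45A, not detected in control 2, was higher by 3.24 ± 0.35. CCM2L, detected on only 1 co-culture array, was at least 1.15-fold higher. These differences were not called (limma, adjusted p between 0.201 and 0.384).

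Genes lower in both co-cultures included 4 of lipid handling or scavenging. FABP4, a fatty acid carrier induced by PPARG, stood at 10.73 and 10.75 in the co-cultures against 15.40 and 13.26 in the controls, 12.1-fold lower (-3.59 ± 0.71). The scavenger receptor gene MSR1 differed by -3.14 ± 0.71 (-3.85 against control 1 alone, -2.43 against control 2 alone), NR1H3, which encodes the oxysterol receptor LXR-alpha, was 5.13-fold lower (-2.36 ± 0.37) and the apolipoprotein gene APOC1 was 4.30-fold lower (-2.10 ± 0.33). The small heat shock protein gene HSPB7 was 6.82-fold lower, the stress gene GADD45A 4.56-fold and RAB7B, a late endosomal GTPase gene, 4.18-fold. PSEN2, a presenilin gene not detected on 1 co-culture array, differed by -2.78 ± 0.63 (-3.67 and -1.89 against each control alone). SHPRH and DPYSL3, not detected on either co-culture array, were at least 1.20-fold and at least 1.53-fold lower. None passed the threshold (limma, adjusted p between 0.201 and 0.384).

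**Figure D1:**
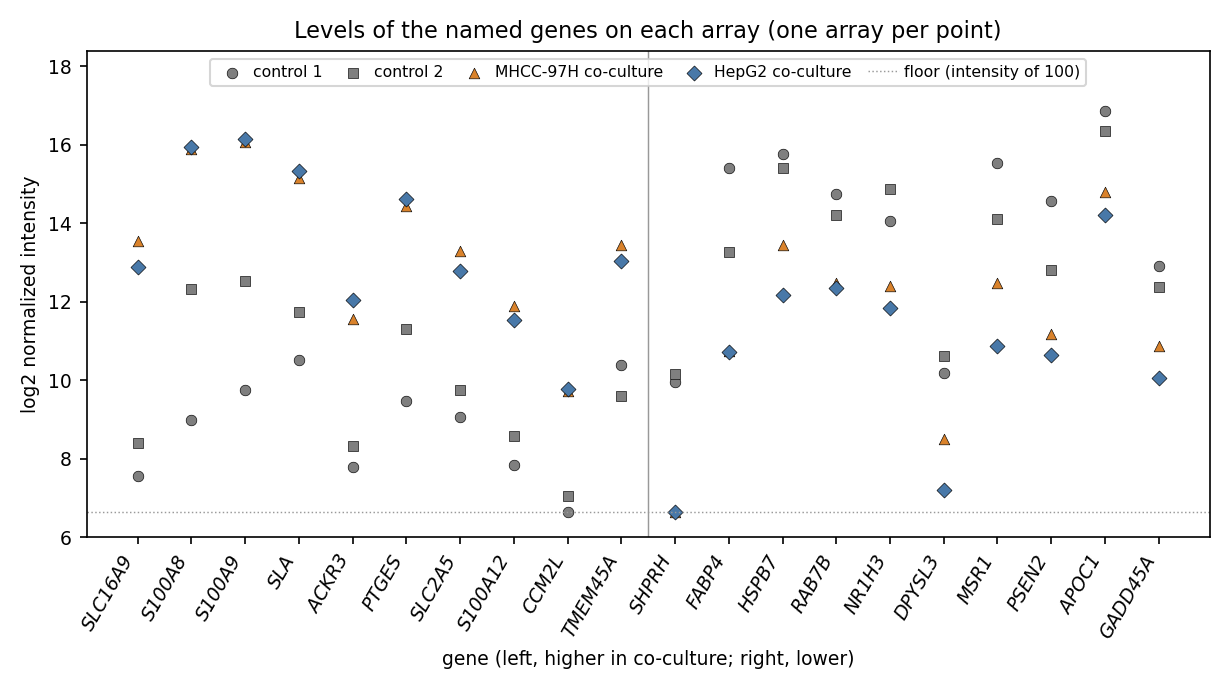
Levels (log2 normalized intensity, y axis) of the 20 genes named for the joint comparison (x axis), with 1 point per array and the floor at an intensity of 100 as a dotted line. Both co-culture points lie above both controls for the 10 genes on the left and below them for the 10 on the right, and for S100A8 control 2 lies 3.32 above control 1.

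Hypoxia and glycolysis genes were higher as a group. Of 25 measured members 21 lay above both controls on both co-culture arrays and 1 below, with a median difference of 1.08. Over all 11010 genes 2672 lay above in this way and 2816 below, the background for such counts in every list. ALDOC, a glycolytic aldolase gene, differed by 2.91 ± 0.35, the mitophagy gene BNIP3 by 2.12 ± 0.49, NDRG1 by 2.02 ± 0.38 and the glucose transporter gene SLC2A3 by 1.94 ± 0.27. No member passed over all genes, and 13 passed when adjusted over the list alone. The list was called by camera (adjusted p = 3.16e-12), and not with an estimated correlation (adjusted p = 0.563). Between the controls the same list already differed by a median of 0.62, higher in control 2.

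Interferon-stimulated genes were higher under both lines, with 26 of 29 measured members above both controls on both co-culture arrays and none below. IFIT1 and IFIT2, which encode antiviral RNA-binding proteins, differed by 4.22 ± 1.91 and 3.72 ± 1.14, IFI44L by 3.55 ± 1.68 and OASL by 3.45 ± 1.22, all 4 not detected in control 1, so that these sizes depend on dim signal there. The size depended on the pair: the list median was 3.84 for HepG2 minus control 1 and 0.74 for MHCC-97H minus control 2, while control 2 exceeded control 1 by 2.36. The joint median of 2.27 became 0.88 without control 1 and 3.66 without control 2. The list was called (camera, adjusted p = 9.88e-12; adjusted p = 0.563 with an estimated correlation), and 0 members passed when adjusted over the list alone. Camera gave a smaller adjusted p, 6.81e-16, for HepG2 with control 2 against the other arrays, so this call is not particular to co-culture.

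Inflammatory genes were higher in part. In the cytokine and chemokine list 12 of 23 members lay above both controls on both co-culture arrays, led by the neutrophil chemokine gene CXCL5 (4.87 ± 2.34), the cyclooxygenase gene PTGS2 (4.81 ± 2.55), IL6 (4.45 ± 1.59) and IL1A (3.34 ± 1.09). PTGS2 stood at 9.75 in control 1, 17.81 in control 2, 18.69 under MHCC-97H and 18.49 under HepG2, so most of its difference lay between the controls. The joint median of the list, 1.35, became 0.27 without control 1 and 3.24 without control 2. Among classical (M1-type) markers 9 of 13 lay above, with TNFSF10, the gene of the death ligand TRAIL, at 3.88 ± 0.73, CXCL10 at 2.43 ± 1.04 and the guanylate-binding protein gene GBP5, which was not detected in either control, and 5 passed when adjusted over the list alone. The M1-type median of 1.74 became 0.88 without control 1. For NF-kB targets only 6 of 21 lay above, near the share over all genes (2672 of 11010). Members with large differences were TNFAIP6 (3.87 ± 1.86) and SOD2 (1.65 ± 1.11). IL6, TNFSF10, CXCL10 and TNFAIP6 were not detected in control 1. CXCL10 stood at 10.82 and 11.71 in the co-cultures against 10.38 in control 2, so only the lower of these was close to control 2. The 3 lists were called by camera (adjusted p = 1.08e-05, 4.75e-06 and 0.0063), with adjusted p = 0.611, 0.563 and 0.613 with an estimated correlation. Without control 1 the NF-kB list turned direction in that test (adjusted p = 0.88). For HepG2 with control 2 against the other arrays, camera gave the cytokine, M1-type and NF-kB lists adjusted p = 8.09e-07, 6.73e-05 and 2.59e-11. The cytokine and NF-kB calls were thus stronger for that grouping than for the real one.

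Metallothionein genes, which encode zinc-binding proteins, were higher in both pairs, by medians of 2.88 for HepG2 and 1.35 for MHCC-97H. Control 2 exceeded control 1 by 1.90, more than the MHCC-97H pair differed, and the joint median of 2.10 became 1.21 without control 1. All 6 measured members lay above both controls on both co-culture arrays, among them MT1F (2.78 ± 0.79), MT2A (2.62 ± 0.84), MT1G (2.16 ± 0.76) and MT1X (2.04 ± 0.48), and 5 passed when adjusted over the list alone. Secreted growth factor genes included INHBA, the activin A subunit gene (4.08 ± 1.73), FGF2 (2.61 ± 1.12), WNT5A (2.58 ± 1.23) and ANGPTL4 (2.36 ± 0.37), with 9 of 18 members above and 3 below both controls. FGF2 and WNT5A were not detected in control 1, nor FGF2 under HepG2. The lists were called by camera (adjusted p = 0.000207 and 0.0378), with adjusted p = 0.563 and 0.613 with an estimated correlation. Without control 1 the growth factor list was no longer called (adjusted p = 0.197).

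Lower lists covered lipids, mitochondria, ribosomes and proliferation. In the lipid, LXR and PPARG list 12 of 21 members lay below both controls on both co-culture arrays and 4 above, with FABP4 and NR1H3 as given, the fatty acid receptor gene CD36 at -3.04 ± 0.80 and, on the other side, ANGPTL4 at 2.36 ± 0.37. Of 35 oxidative phosphorylation genes 24 lay below and 1 above, by a median of -0.45, with ATP5PB at -1.09 ± 0.27 and SDHB at -0.81 ± 0.24. Of 44 ribosomal protein genes 20 lay below and 0 above, with RPSA, not detected under HepG2, at -1.17 ± 0.33. Of 23 cell cycle genes 13 lay below and 2 above, with the mitotic gene CDC20 at -1.89 ± 0.53, and their median of -0.47 became -0.21 without control 1. The 4 lists were called by camera (adjusted p = 0.00518, 1.08e-05, 0.00144 and 0.0168), and none with an estimated correlation (adjusted p = 0.563, 0.563, 0.613 and 0.563). For the lipid list the estimated correlation was -0.001, under the preset 0.01. There the loss came from the few degrees of freedom and not from correlation between genes. Without control 1 the ribosomal list was not called either (adjusted p = 0.282).

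Alternative (M2-type) markers had 7 of 22 members above both controls on both co-culture arrays, including the decoy receptor gene IL1R2 (4.55 ± 1.45), and 3 below, MSR1, CD36 (-3.04 ± 0.80) and the efferocytosis receptor gene MERTK (-2.36 ± 0.66). Control 2 lay nearer the co-cultures for each: IL1R2 was at 12.66 in control 2 and not detected in control 1, CD36 at 14.48 against 16.77 and MERTK at 12.53 against 14.46. Their median lay above the range of matched random lists in the HepG2 pair (0.38) and in the MHCC-97H pair (0.31), but HepG2 minus control 2 gave -0.11. Tumour-associated macrophage markers had 6 of 24 members above and 9 below both controls, with LGMN (1.90 ± 0.44) and VEGFA (1.88 ± 0.43) above and FABP4 and APOC1 below. Their median lay below the random range in the HepG2 pair (-0.73) and inside it in the MHCC-97H pair (-0.03). With the controls exchanged it was -0.09 for HepG2 and -0.48 for MHCC-97H, so this contrast between the lines turned with the control used. Macrophage differentiation markers had 6 of 28 above, including the lipopolysaccharide co-receptor gene CD14 (3.31 ± 0.69), and 11 below. The counts above in these 3 lists (7 of 22, 6 of 24 and 6 of 28) lay near the share over all genes, 2672 of 11010. The S100 list had 8 of 17 above, and beyond S100A8, S100A9 and S100A12 its largest change was CD36. None of the 4 lists was called (camera, adjusted p = 0.0851, 0.34, 0.484 and 0.0563). The M2-type list was called with the array pair as a block (adjusted p = 0.0108; adjusted p = 0.787 with an estimated correlation) and without control 2 (adjusted p = 0.0342), and the S100 list without control 1 (adjusted p = 0.000282).

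Markers of other cells were few. Of 31 hepatocyte and hepatoma genes 7 were measured above the detection threshold and the list was not called (camera, adjusted p = 0.432); its largest change was SERPINA1, an antiprotease gene detected under MHCC-97H only, at 11.54 under MHCC-97H and 9.63 under HepG2 against 8.36 and 9.33. Epithelial markers had 7 of 17 genes measured (adjusted p = 0.919). Neutrophil and granule markers were called (adjusted p = 0.00518; adjusted p = 0.563 with an estimated correlation) on 6 of 14 genes, of which 4 lay above both controls on both co-culture arrays, among them S100A12 and BPI, neither detected in the controls. Markers of undifferentiated THP-1 cells or myeloid progenitors had 4 of 11 members below both controls on both co-culture arrays and 1 above, and were not called (adjusted p = 0.127; 0.215 without control 1 and 0.00305 without control 2). Their median differed more between the controls (-1.36, control 2 minus control 1) than in the HepG2 pair (-0.91) or the MHCC-97H pair (-0.25). The largest change was the granule gene AZU1 at 15.44 in control 1, 12.04 in control 2, 11.04 under MHCC-97H and 10.72 under HepG2. Immediate early and heat shock genes, which respond to handling, differed by a median of -0.05 (adjusted p = 0.919), a sign that turned under quantile normalization (0.01).

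The remaining lists were not called in the joint comparison with all 4 samples. ER stress and amino acid response genes had DDIT4, an inhibitor of mTORC1 signalling, at 2.25 ± 0.45 and the secreted stress factor gene GDF15 at -1.78 ± 0.39 (camera, adjusted p = 0.52). NRF2 and haem response genes had TXNRD1 at -1.02 ± 0.27 and HMOX1 at -1.02 ± 0.23 (adjusted p = 0.0887), and this list was called without control 1 (adjusted p = 0.019). The adjusted p was 0.22 for dendritic and osteoclast-like markers, 0.432 for MHC class II and antigen presentation, 0.722 for cholesterol synthesis and 0.919 for matrix and protease genes, whose test pointed lower while their median was 0.01.

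Over all genes the joint comparison called 0 of 11010 (limma, smallest adjusted p = 0.201), and 1377 had an unadjusted p under 0.05. Independent genes without any change would give 550. The same test gave 529 for HepG2 with control 1 against the other arrays and 27 for HepG2 with control 2 against the others. The number 550 is therefore a poor yardstick for these correlated genes. At 2-fold in all 4 differences between a co-culture and a control, 201 genes stood apart, 121 higher and 80 lower, and after median centring of the raw intensities, chosen for these counts after seeing the data, the split was 94 higher and 108 lower. Without control 1 the count was 294 and without control 2 it was 1308. For many genes named here control 2 lay nearer the co-cultures than control 1 did, so their differences from control 2 alone are smaller than the joint ones, as for INHBA, WNT5A, SOD2, CXCL5, IL1A, CD14, CDC20 and MT1F. The 0 calls rest on the distance between the controls: without control 1 the test called 15 genes and without control 2 it called 962, with the lone control assumed to vary like the co-cultures. Camera at its preset correlation called 12 of 26 lists for the real grouping, and also 4 lists for HepG2 with control 1 against the other arrays and 13 lists for HepG2 with control 2 against the others, so a camera call alone does not separate the co-cultures from other groupings of these arrays. The last grouping gave the interferon, cytokine, NF-kB, growth factor and ribosomal lists smaller adjusted p than the real grouping. The other lists called for the real grouping had larger ones there.

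**Figure D2:**
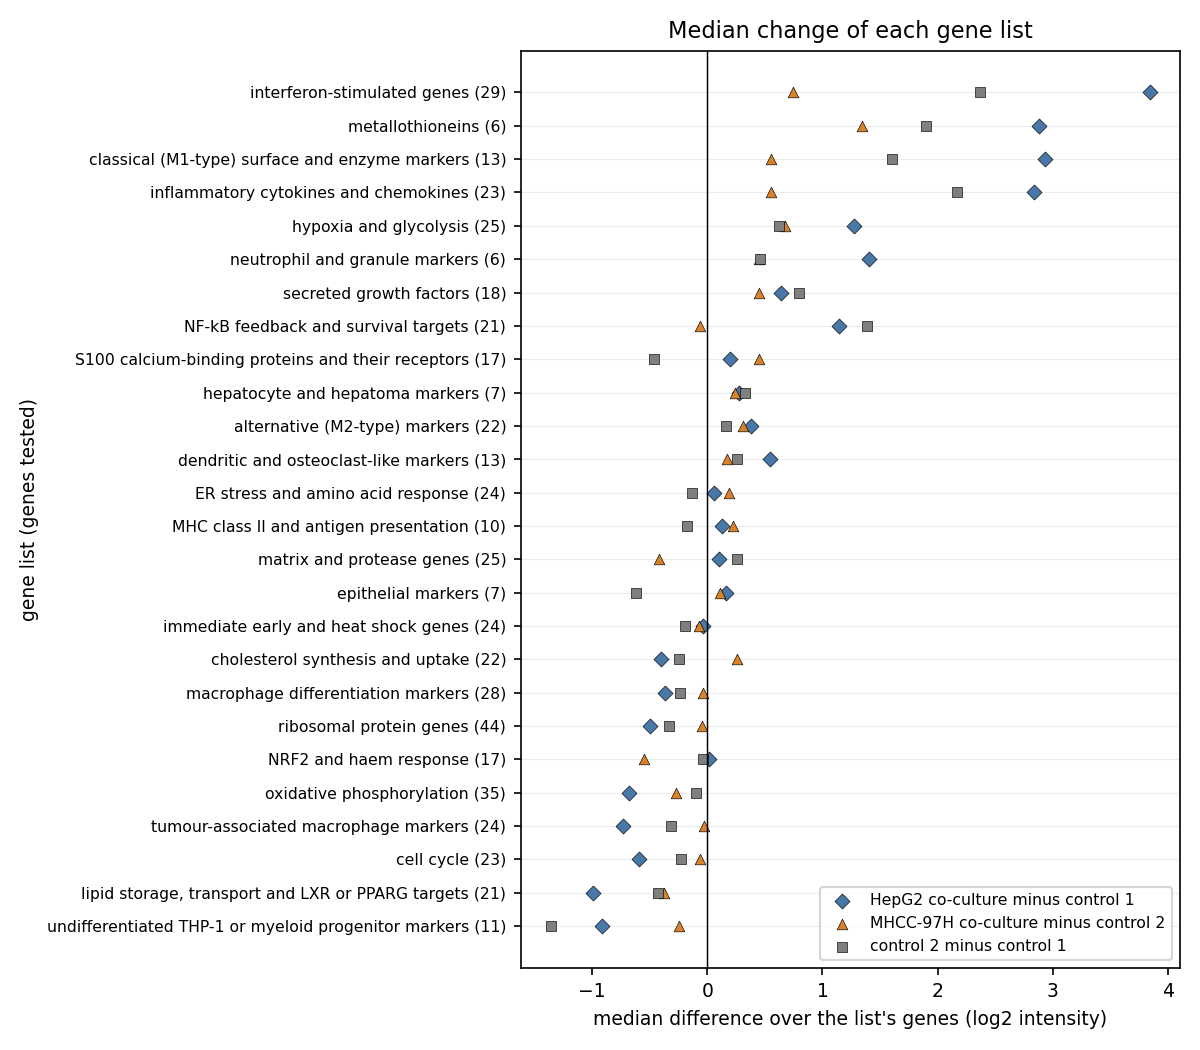
Median log2 difference (x axis) of each gene list (y axis, genes tested in brackets) for the HepG2 co-culture minus control 1, the MHCC-97H co-culture minus control 2 and control 2 minus control 1. The interferon list lies at 3.84, 0.74 and 2.36, and the hypoxia list at 1.27, 0.67 and 0.62.

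The HepG2 comparison asked what this line did on its own. Beyond the genes above, HepG2 co-culture had high levels of TNFSF10, at 14.07 against 8.63 in control 1, where it was not detected, and 10.00 in control 2 (4.76 ± 0.71). The interferon-induced membrane protein gene IFITM1 stood at 16.39 against 10.19 and 12.45 (5.07 ± 1.11). The mitochondrial iron importer gene SLC25A37 was higher by 3.70 ± 0.35. SULF2, a heparan sulfate sulfatase gene, and HSH2D, both not detected in the controls, were at least 2.01-fold and at least 3.28-fold higher. On the lower side MSR1 stood at 10.87 against 15.54 and 14.11 (-3.95 ± 0.73) and HSPB7 was 10.6-fold lower (-3.41 ± 0.35). CLDND1, PRMT6, an arginine methyltransferase gene, KIF19, RBSN and RPRD2 stood near the controls under MHCC-97H and were at least 12.4-fold, 2.44-fold, 2.42-fold, 3.18-fold and 2.16-fold lower under HepG2, where their probes were not detected. Each of these rests on a single probe on a single array, and second probes were not compared. A probe defect on the HepG2 array cannot be told apart from lower expression there.

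The test called 0 genes for HepG2 (limma, smallest adjusted p = 0.796), with 662 at an unadjusted p under 0.05. At least 2-fold from both controls were 597 genes, 303 higher and 294 lower, and the count was 1097 against control 2 alone and 1854 against control 1 alone. Camera called 11 of the 26 lists and 0 with an estimated correlation (smallest adjusted p = 0.733). With 1 HepG2 sample, simulated changes of 4 on the log2 scale were never recovered, so the 0 calls say little about effects of that size.

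Under MHCC-97H the inflammatory cytokine gene IL6 reached 14.48, against 11.01 in control 2 and 12.08 under HepG2, and it was not detected in control 1, so its difference (5.65 ± 2.08) depends on the floor. TMEM45A, not detected in control 2, was higher by 3.44 ± 0.47, and SLC2A5 was at least 13.3-fold higher. PTGES stood at 14.43 against 9.47 and 11.31 (4.05 ± 0.92), and FABP4 at 10.75 against 15.40 and 13.26 (-3.58 ± 1.05). FABP3, the heart-type fatty acid carrier gene, and NXN, the nucleoredoxin gene, lay at the floor and were at least 1.57-fold and at least 1.21-fold lower. Under HepG2 they stood at 10.10 and 10.12, near control 2 (10.18 and 9.98), though NXN was not detected there. Second probes were not compared, so a probe defect on the MHCC-97H array cannot be told apart from lower expression. The potassium channel subunit gene KCNMB4 was at least 3.69-fold lower. NRF2 and haem response genes had a median of -0.55 against control 2, outside the range of -0.27 to 0.23 of matched random lists, with TXNRD1 at 13.86 against 15.22 and HMOX1 at 13.46 against 14.28. That list was called for MHCC-97H (camera, adjusted p = 0.00978; adjusted p = 0.718 with an estimated correlation) and not for HepG2 (adjusted p = 0.495), but its median difference between the lines, 0.13, lay inside the random range of -0.25 to 0.14.

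For MHCC-97H the test called 0 genes (limma, smallest adjusted p = 0.8), with 329 at an unadjusted p under 0.05. At least 2-fold from both controls were 346 genes, 180 higher and 166 lower, a split that became 134 and 242 after median centring, and the count was 469 against control 2 alone and 2003 against control 1 alone. Camera called 12 of the 26 lists and 0 with an estimated correlation (smallest adjusted p = 0.718).

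Between the co-cultures 512 genes were at least 2-fold apart, 337 higher under HepG2 and 175 lower, with 0 called (limma, smallest adjusted p = 1; 139 at an unadjusted p under 0.05). Several of the largest differences belonged to genes that split the controls the same way. UBB, a ubiquitin gene, stood at 16.67 under HepG2 and 16.87 in control 1 and at the floor on both other arrays. HTRA1, a serine protease gene, and DLK1, a Notch-family ligand gene, were high with control 1 and HepG2, and LARP4B, the cathepsin G gene CTSG and the granzyme gene GZMB with control 2 and MHCC-97H. P3H1 was at the floor under MHCC-97H only (9.70, 13.52 and 13.24 on the other arrays), TCIM was detected under HepG2 only, MMP12, the macrophage elastase gene, was 7.72 under HepG2 against 12.40 under MHCC-97H, and KIF19 was 7.19 against 10.98. Of the gene lists, 7 lay below the range of matched random lists: hepatocyte markers (-0.42), cholesterol synthesis (-0.39), inflammatory cytokines (-0.38), metallothioneins (-0.37), cell cycle (-0.31), M2-type markers (-0.29) and ribosomal proteins (-0.21). Dendritic and osteoclast-like markers were higher by 0.49 and interferon-stimulated genes by 0.17, the 2 lists above it. These describe 2 single arrays and have no replicate check. Between the 2 controls, which share all labels, 9 lists lay above the random range and 8 below it.

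Within the authors' array pairs, 1854 genes were at least 2-fold apart for HepG2 and control 1 (847 higher, 1007 lower) and 469 for MHCC-97H and control 2 (238 higher, 231 lower; 182 and 341 after median centring). The 2 controls, which share all labels, differed at 2-fold for 1306 genes (549 higher and 757 lower in control 2). Although the pairs share no array, 171 genes were higher and 122 lower in both (135 and 182 after median centring), where independent lists would share 18.3 and 21.1, and 11 went opposite ways. Across genes the changes in the pairs correlated at r = 0.559, and 69.6% had the same sign, while with the controls exchanged, again without a shared array, r was 0.155 and 350 genes went the same way in both (190 higher, 160 lower). Genes are not independent replicates. The authors called 988 probes higher and 1165 lower for HepG2, and 222 and 244 for MHCC-97H, with 167 and 119 called the same way in both. The authors' deposited table gives S100A9 a log2 ratio of 6.50 (p = 9.59e-07) in the HepG2 pair and 3.53 (p = 6.71e-06) in the MHCC-97H pair, p-values that compare 2 arrays without replicates.

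**Figure D3:**
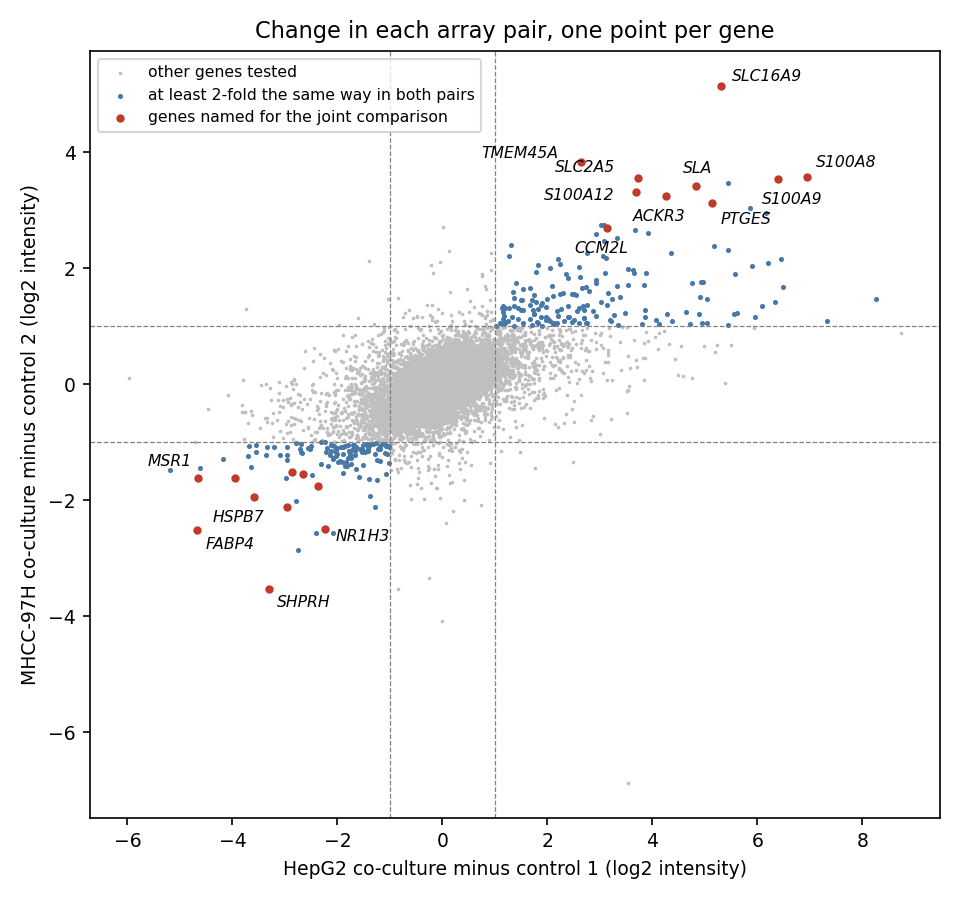
Log2 change of each gene tested in the HepG2 pair (x axis) and in the MHCC-97H pair (y axis), 1 point per gene, with the genes named for the joint comparison in red and dashed lines at 2-fold. The 171 genes higher and 122 lower in both pairs lie in the outer corners, with S100A8 at 6.95 and 3.57.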

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

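For this part, the tests of mixed RNA, of handling stress, of carried-over cancer cells and of the genes not detected on all arrays were chosen only after the result was seen. The tests on second probes and on the share of genes detected on all 4 arrays had their predictions written before their results.

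Control 1 resembled the HepG2 array, and control 2 the MHCC-97H array, for 118 genes, among them DLK1 (15.33 and 14.51 against 10.50 and 10.66), MLLT11 (16.45 and 16.25 against 12.86 and 12.79) and CD9 (16.73 and 15.29 against 13.28 and 13.15). Defects of single probes were argued against by 23 genes with a second detected probe, of which 21 differed the same way, with a median of 1.6 over all 23 (95% interval 1.4 to 2.46), but the 3 genes at the floor on a pair and detected on both other arrays, such as UBB, had 0 second probes, and there defects cannot be told apart from other causes. Dim probes were argued against by the 41.5% of genes detected on all 4 arrays (49 of 118), yet of the other 69 only 13% lay well above the detection limit (9 genes), which leaves this open for them. A shared culture or processing batch of each pair may account for the resemblance: the arrays split by pair in dim signal too, with 828 and 760 values at or below 0 for control 1 and HepG2 against 0 and 8 for control 2 and MHCC-97H, but no label names a batch. No biological explanation was tested.

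Control 2 lay between control 1 and the co-cultures for interferon and inflammatory genes, as for IFIT1 (8.71 in control 1, 14.71 in control 2, 15.81 under MHCC-97H). If co-culture RNA had been mixed into control 2, the share needed should be alike for all genes. Over 126 genes its 90th percentile was 5.04 times its 10th (95% interval 3.93 to 8.45), a spread that alone does not decide. Only genes detected in control 2 entered, which left out genes such as SLC16A9. The share was 7.6% for S100A8, 7.5% for S100A9, 46.4% for IFIT1 and 35.8% for CXCL5, with a median of 48.4%. A mix large enough for IFIT1 would have put more S100A8 and S100A9 into control 2 than was measured. This argues against mixing as the whole difference for IFIT1 and CXCL5, while a smaller mix stays open. Handling stress stays open as well: immediate early and heat shock genes differed between the controls by a median of -0.19 (95% interval -0.39 to 0.12), but members went both ways, which decides nothing. Activation of the macrophages in control 2 by something in the culture could also raise these genes, and was not tested.

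Both co-cultures stood apart from both controls, and cancer cells carried through or around the membrane would add their own RNA. Of 9 probes for abundant liver and epithelial markers, 0 were detected and at least 4-fold above both controls on the HepG2 array, which argues against it there. On the MHCC-97H array 1 was, a SERPINA1 probe 2.21 above the higher control on the log2 scale. The other SERPINA1 probe was detected there too, but only 0.73 above. Carry-over cannot be told apart from expression by the macrophages on that array. ALB, TTR, FGB and KRT8 were detected on no array. A response to the cancer cells, which the design names, remains open and untested against the handling of the transwells, since the labels do not say whether the controls had an empty insert. The labels as recorded here also give 48 h for the co-cultures and no such time for the controls. A difference in culture time after PMA therefore cannot be told apart from co-culture.

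A difference between the lines drew attention to 3 genes with the co-cultures on opposite sides of both controls and 1 list whose pair medians lay outside the range of matched random lists on opposite sides, and none of these differences was tested with replicates. SMYD1, a muscle-type methyltransferase gene, was higher under HepG2 than under MHCC-97H by 2.75, while HepG2 (12.49) hardly differed from control 1 (12.43). SLC27A1, a fatty acid transporter gene, was higher by 2.85. MMP12 differed by -4.68, while MHCC-97H (12.40) hardly differed from control 2 (12.26), and control 1 (9.55) lay below control 2 in the same direction. The cholesterol synthesis list differed by a median of -0.39, but the controls differed by -0.24, and against the other control the medians were -0.12 for HepG2 and 0.04 for MHCC-97H. Among probes without a single gene, which the report leaves out, 13 were at least 2-fold higher on both co-culture arrays than on both controls and 3 were lower, of 1151 detected.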

How the results depend on the processing

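A lower and a higher floor, the detection p of 0.05, normexp correction, median centring of the fold counts and leaving out a control from the list tests and from the counts against both controls were chosen after seeing the data. With all 4 samples each limma alternative that was run called 0 genes, the pair as a block being run for the joint comparison only. All 20 genes named for the joint comparison kept their direction under quantile normalization and normexp. Their direction against each control alone was fixed by how they were chosen. The pair as a block leaves the differences unchanged in this balanced design, so neither of these is a check. Quantile normalization, median centring, no filter, the mean of probes and both floors left the fold counts within 1.5 times, and the deposited value table was run for the limma tests only. With the pair as a block 13 lists were called, and with an estimated correlation 0, which the few degrees of freedom there all but fixed. Few arrays and dim probes limit all counts.

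In the order HepG2 pair, MHCC-97H pair, the 2 controls, both pairs, all 4 differences, HepG2 from both controls and MHCC-97H from both controls, the counts were 1151, 228, 692, 153, 109, 359 and 170 for genes detected on all 4 arrays, where fewer genes are tested. They were 3968, 1890, 2921, 1157, 704, 1659 and 1245 at 1.5-fold, and 786, 116, 560, 72, 48, 189 and 88 at 3-fold, as a lower or higher threshold must give. Crossed pairs gave 1097 for HepG2 and 2003 for MHCC-97H, with 350 genes the same way in both, and the cause was not tested.

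The joint comparison called 15 genes without control 1, 962 without control 2 and 0 without either co-culture; fewer samples hold less of the spread between controls. Without control 1 and without control 2, HepG2 counts were 1097 and 1854, MHCC-97H counts 469 and 2003, and counts over all differences left 294 and 1308. The NF-kB list had a median of 0.01 without control 1, with its test reversed, and 1.13 without control 2, and the cause was not tested.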

Other observations

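The test of the arrays grouped by pair and the ratio of the pair counts were chosen only after the result was seen. The control arrays were less alike than the co-culture arrays: across genes, which are not independent replicates, the controls correlated at r = 0.912 and the co-cultures at r = 0.961, and control 2 with MHCC-97H at r = 0.964. The number of genes at least 2-fold apart in the HepG2 pair was 3.95 times that in the MHCC-97H pair, and 0.55 times with the controls exchanged. UBB, LARP4B and HTRA1 were the only genes called when HepG2 and control 1 were set against the other arrays (limma, adjusted p = 0.00216, 0.011 and 0.0161). UBB and LARP4B lay at 6.64, the floor, on both arrays of a group, and HTRA1 at 6.68 and 6.64. The floor, chosen after seeing the data, narrows the spread on which these calls rest. None of these genes had a second detected probe, so probe defects stay open.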
